A study of Danio rerio with 12 samples.

How the data were processed

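Ovarian RNA of adult female zebrafish of the EK strain was sequenced in 12 libraries, with 3 libraries at each of 0, 1, 3 and 10 ppm methylmercury (MeHg) in the diet. The 0 ppm fish received the ethanol vehicle, and exposure covered the whole life cycle from the mother on. Per the labels' protocols, each library was made from RNA pooled from up to 6 fish with the TruSeq RNA kit, and all 12 were run in a lane as paired-end reads of 100 bases. A p-value here therefore measures the spread between pools, not between single fish.

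Per the submitters' processing notes, the tools were CASAVA 1.8.2, cutadapt, TopHat, Cufflinks 2.2.1 and Cuffdiff, and the genome build was Zv9. Their settings, the gene annotation and any use of strand are not given in the sources used here. The authors deposited, per the file headers, an estimated count of fragments per locus and library before scaling, for 34159 loci. Of these values, 98.9% lay within 0.001 of a whole number. The same deposited table gives FPKM, fragments per kilobase at a common depth, after the authors' scaling between libraries. A second deposited table, kept by the authors to their significant loci, holds a log2 fold change between group FPKM values and a p-value and q-value for each of 507 lines over 6 pairwise comparisons. It has no header line, so its columns were read from their values and the order of Cuffdiff output. The tables of group means, isoforms, start sites and coding sequences, a list of locus numbers and a bias file were not used here, so 9 of the 11 files stayed out.

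The locus table carries locus numbers and no gene names. Only the 282 loci in the authors' table of significant loci have Ensembl identifiers beside them, and 250 of the 282 have at least 1. Of 275 identifiers, 208 matched a symbol, which named 193 loci; upper-case symbols are printed as the name table gives them. Several identifiers share a locus in 18 cases, and such a locus, for example gbgt1l4/gbgt1l8, cannot be divided between its genes. Near-identical copies, such as the trypsin and elastase genes, may also share reads. Positions are printed on Zv9 as the authors' table gives them, and whether that table counts from 0 or 1 is not stated. In the locus table the libraries of a group are numbered from 0, and these were taken in number order as replicates 1 to 3. No label states this correspondence, so the group of each library is certain and its replicate number is a name only.

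Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The fit used TMM scaling, the filterByExpr filter, which left 15916 loci, and the quasi-likelihood test on all 12 libraries, so that all groups shared an estimate of the spread. Each dose was compared with 0 ppm, the 3 doses were tested jointly, and a slope on log2(dose in ppm + 1) was fitted. Adjusted p-values are Benjamini-Hochberg values over all tested loci, and the threshold was 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD of 3 libraries. All p-values are two-sided.

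Genes to be named were fixed before the data were examined. Per dose these were to be up to 12 rising and 12 falling genes that had a symbol, passed the threshold, reached 1 CPM and had all 3 exposed libraries on one side of all 3 controls. Where none qualified, the 10 genes with a symbol and the smallest p were to be named as not past the threshold, and this applied at all 3 doses and, by the same rule, to the slope, for which 9 of the 10 are given. Up to 4 members of each gene list were to be named by their p; the list of other organs is named in full, beyond that rule. The 25 gene lists were also fixed in advance from textbook knowledge. Because names exist only for loci that the authors had called on these same samples, the lists are not independent evidence. The list test, limma 3.58.1 camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, was planned against all loci. It was run instead against the 181 tested loci with a symbol, since unnamed loci could hold unrecognised members. It covered the 6 lists with at least 3 named members, all of which kept at least 3 tested members. Values were adjusted over the 18 combinations of list and dose.

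The fits were tested on simulated counts before use. Counts were drawn from the real locus means, library sizes and dispersions, with 200 changed loci in each of 5 simulations per dose over 15630, 15635 and 15641 loci at 1, 3 and 10 ppm. Of 2-fold changes, 55.2% were recovered at 1 ppm, 49% at 3 ppm and 56.1% at 10 ppm; of 4-fold changes, 81.8%, 78.8% and 79.4%. Of 1.5-fold changes, 29%, 19.4% and 27.5% were recovered. False calls made up 3.7%, 5% and 6.4% of calls. The simulation carried no library with a different tissue make-up.

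Library totals ran from 3727213 fragments (3 ppm replicate 1) to 9669846 (1 ppm replicate 1). A count of 3 fragments corresponded to 0.31 CPM in the deepest library and 0.805 CPM in the shallowest. Replicates of a group differed by 6.76 to 18.26 in chi-square per degree of freedom, so no pair resembled a library entered more than once. Alternatives tried were DESeq2 1.42.0, its size factors in edgeR, other filters, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, fits on 6 libraries, other dose scales, removal of the 5 loci whose status was not OK in some library, and removal of each library in turn. DESeq2 for loci called at more than 1 dose and for the authors' calls, and the ratios of list members without single libraries, were added after seeing the data. These ratios are log2 ratios of group mean CPM, with 0.5 CPM added. Figures were drawn with matplotlib.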

Results

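Ovarian transcript abundance was measured in zebrafish fed MeHg, an organic mercury compound that crosses into eggs, at 1, 3 or 10 ppm or the vehicle alone. Each group had 3 libraries of pooled ovarian RNA. Library totals were 5833328, 8179604 and 7134835 fragments at 0 ppm and 9669846, 5508246 and 6293321 at 1 ppm. They were 3727213, 7604383 and 7664397 fragments at 3 ppm and 5945033, 8292908 and 6202124 at 10 ppm. The libraries did not group by dose over all loci. The mean distance between libraries of a group was 75.9 ± 6.8 (SD, 12 pairs) on the log2 CPM scale, and between groups it was 75.8 ± 6 (SD, 54 pairs). The first principal component held 16.1% of the variance and placed 10 ppm replicate 1 at 50.4 and the other 11 libraries between -33.8 and 13.4.

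The first comparison asked which ovarian genes differed at 1 ppm. The gene with the smallest p was zgc:153499, on chromosome 9 from 8449880 to 8453901, at 1030 ± 109 CPM against 665 ± 38.8 CPM at 0 ppm (SD, n = 3 each). Its log2 fold change was 0.63 with a standard error of 0.10, and its edgeR adjusted p was 0.30. The glycosyltransferase-like locus gbgt1l4/gbgt1l8, on chromosome 5 from 25426867 to 25474322, stood at 183 ± 47.7 CPM against 441 ± 129 CPM, a log2 fold change of -1.27. The deubiquitinase gene usp43b, on chromosome 3 from 25648468 to 25747094, stood at 12 ± 1.87 CPM against 4.27 ± 0.0387 CPM, a log2 fold change of 1.48. Transcripts of selenos, which encodes a selenoprotein of the endoplasmic reticulum, stood at 68.6 ± 8.41 CPM against 103 ± 7.71 CPM. None of these genes passed the threshold.

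Among the remaining genes named at 1 ppm, higher means were found for MRPS23, a protein of the mitochondrial ribosome (log2 fold change 0.52), si:ch211-226h8.4 (0.51), the transporter gene ABCC12 (0.93) and the interleukin-13 receptor gene il13ra2 (0.93). Lower means were found for zgc:63972 (-1.46) and RPP25L, a relative of a ribonuclease P subunit (-0.77). In all 10 named genes the 3 exposed libraries lay beyond the 3 controls, which chance gives for 10% of genes before selection by p. Their edgeR adjusted p-values ran from 0.30 to 0.64. No locus of 15916 passed at 1 ppm by edgeR, while 1137 had an unadjusted p under 0.05, 523 higher and 614 lower, where 796 would be expected by chance. That count was 601 without 1 ppm replicate 1 (813 expected) and 2090 without 1 ppm replicate 2 (830 expected), and limma on log2(FPKM + 1) gave 547 higher and 445 lower. DESeq2 called 19 loci, 9 higher and 10 lower, among them zgc:153499 (adjusted p 2.09e-06; 2.09e-06 to 0.831 over its 22 alternatives), gbgt1l4/gbgt1l8, usp43b, zgc:63972 and si:ch211-226h8.4. When 1 ppm replicate 2, 3 ppm replicate 2 and 10 ppm replicate 1 were left out, a choice made after seeing the data, edgeR called 130 loci at 1 ppm, 19 higher and 111 lower, among them CYP19A1 and selenos. Of all 27 ways to leave 1 library out of each exposed group, 5 gave any call at 1 ppm, the median was 0 and the highest other count was 96.

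At 3 ppm the gene with the smallest p among those with a symbol was si:ch211-5k11.8, on chromosome 3 from 55950129 to 55957631. It stood at 15.6 ± 1.92 CPM against 6.63 ± 0.594 CPM (SD, n = 3 each), a log2 fold change of 1.23. The chemokine gene ccl25b stood at 3.93 ± 0.903 CPM against 9.99 ± 4.09 CPM, and SLIT3, a secreted guidance ligand, at 4.41 ± 0.806 CPM against 8.28 ± 0.176 CPM. Higher means were also found for ugt2a4, a glucuronosyltransferase of detoxification (log2 fold change 0.86), GANAB, a glucosidase of glycoprotein folding (1.09), the activin and nodal receptor gene ACVR1C (0.99) and the ribosomal protein gene RPS12 (0.52). Lower means were found for TBC1D24 (-0.84), tex2l (-1.05) and the caspase gene casp23 (-0.67). All 10 had an edgeR adjusted p of 0.93. In 7 of the 10 the 3 exposed libraries lay beyond the controls. Without a single library the log2 fold change was 0.45 for GANAB (3 ppm replicate 3), 0.52 for ugt2a4 (3 ppm replicate 1), -0.60 for tex2l (3 ppm replicate 3) and -0.42 for casp23 (3 ppm replicate 2). No locus passed at 3 ppm by edgeR, 745 had an unadjusted p under 0.05 (469 without 3 ppm replicate 2), and DESeq2 called 2, both higher. These were ENSDARG00000004541 (log2 fold change 2.97) and a locus without a name, both chosen here after their values were seen. The latter had 682 and 409 fragments in 3 ppm replicates 2 and 3, 679 in 1 ppm replicate 1 and 0 in the other 9 libraries, so its fitted log2 fold change of 23.83 is not a measured size.

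At 10 ppm, the highest dose, zgc:153738 had the smallest p. It lies on chromosome 8 from 18969451 to 19019038 and stood at 50.5 ± 8.71 CPM against 87.9 ± 15 CPM at 0 ppm (SD, n = 3 each), a log2 fold change of -0.80. ACVR1C stood at 9.26 ± 2.44 CPM against 2.83 ± 0.798 CPM, a log2 fold change of 1.68, and GANAB at 17.9 ± 1.63 CPM against 5.99 ± 1.59 CPM, a log2 fold change of 1.59. The purine salvage enzyme gene PNP stood at 20 ± 7.83 CPM against 9.82 ± 0.864 CPM. The signalling gene BCR stood at 38.6 ± 7.88 CPM against 20.2 ± 4.88 CPM. Higher means were also found for zgc:153499 (log2 fold change 0.44), the smooth muscle actin gene acta2 (0.70), ABCC12 (0.85, and 0.51 without 10 ppm replicate 1), ugt2a4 (0.88) and the transcription factor gene ETV4 (0.77). In 9 of these 10 genes, acta2 being the exception, the 3 libraries at 10 ppm lay beyond the controls. All 10 had an edgeR adjusted p of 1, no locus passed, and 681 had an unadjusted p under 0.05 where chance gives 796. DESeq2 called 4: zgc:153738 (adjusted p 0.0051; 0.0051 to 1 over its 22 alternatives), ACVR1C and zgc:153499 (0.041 each; 0.041 to 1), and ENSDARG00000004541, named after its values were seen.

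**Figure D1:**
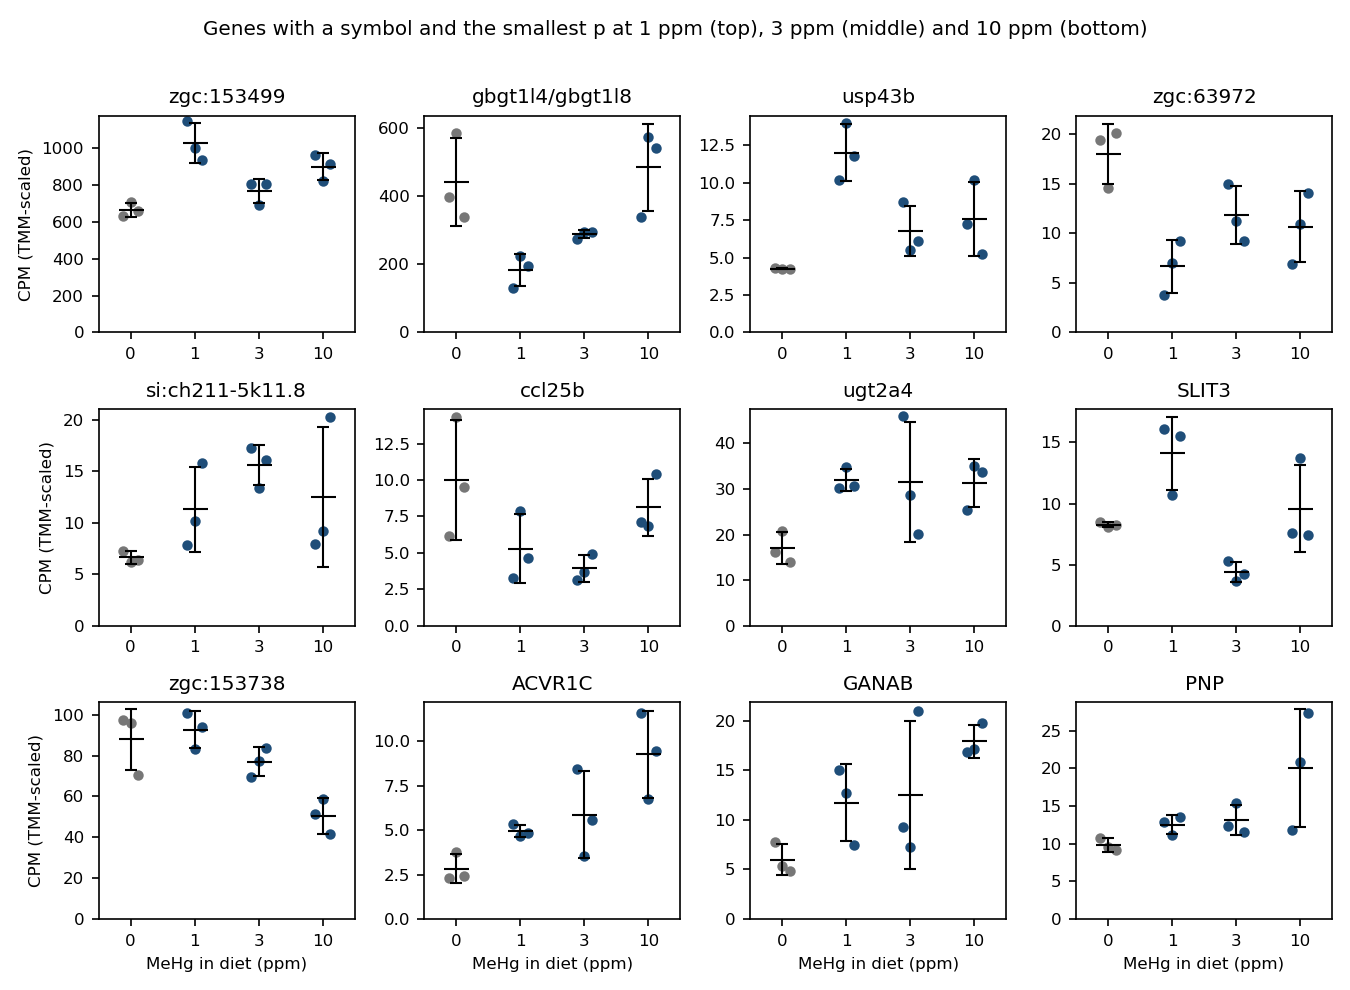
TMM-scaled CPM (y axis, from 0) of 12 named genes against MeHg in the diet in ppm (x axis, categories); points are libraries, grey at 0 ppm and blue at the other doses, and bars are the mean ± SD of 3 libraries. zgc:153499 stands at 1030 CPM at 1 ppm against 665 at 0 ppm, and ACVR1C at 9.26 CPM at 10 ppm against 2.83, and none of the 12 genes passed the edgeR threshold.

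A joint test asked whether any dose differed from the vehicle, and a slope test asked for a change along the doses. ACVR1C had the smallest p for the slope, with means of 2.83 ± 0.798, 4.95 ± 0.355, 5.87 ± 2.46 and 9.26 ± 2.44 CPM at 0, 1, 3 and 10 ppm (SD, n = 3 each). Its log2 abundance had a slope of 0.45 per unit of log2(dose + 1), with a standard error of 0.09 and an edgeR adjusted p of 0.90. The slope was -0.24 for zgc:153738, 0.28 for PNP, 0.40 for GANAB, 0.20 for acta2 and 0.28 for BCR. RBP2, abundant in gut, had a slope of 0.97, with a large spread at 10 ppm (13.2 ± 19.7 CPM) that came from replicate 1, at 35.9 CPM. ETV4 had a slope of 0.20 and si:dkey-238c7.13 of 0.55. The latter gene stood at 98.9 CPM in 10 ppm replicate 1, against 15.4 and 10 CPM in the other libraries at 10 ppm. Neither edgeR test called a locus; the joint test had 1140 loci and the slope 618 (339 higher, 279 lower) with an unadjusted p under 0.05. The joint count was 1927 without 1 ppm replicate 2, and the slope count 945 without 0 ppm replicate 2. For the slope, limma on log2(FPKM + 1) gave 266 higher and 379 lower. DESeq2 called 37 loci in the joint test and 2 for the slope, zgc:153738 and ACVR1C, and edgeR called 10 in the joint test without the 3 libraries named above.

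Of the 25 gene lists fixed in advance, 6 had at least 3 named members, 9 had 1 or 2 and 10 had none. Single libraries were left out in turn for the 36 tested members. With 0.5 CPM added, leaving out 1 of 6 libraries took over 50% of the log2 ratio of group means from 24, 26 and 30 of them at 1, 3 and 10 ppm, and turned the sign of 16, 15 and 12. A ratio near 0 meets these rules easily, as for COL1A1 at 1 ppm (-0.02), so the counts overstate the weight of single libraries. The ratio of CEL went from 2.49 to 2 at 1 ppm without 0 ppm replicate 1. At 10 ppm it went from 3.65 to 1.46 without 10 ppm replicate 1. None of the 6 passed camera at any dose. Camera compared each list with the other tested loci that have a symbol, all called by the authors on these same samples. This background was itself selected, so the result does not show that the lists were unmoved. A pass is weak evidence too. When the libraries were drawn at random into other groups, some list passed camera with the preset correlation in 61 of 99 draws. The members had all been picked by the authors from these libraries, so their direction is not independent evidence. Adjustment over a list alone leaves out this selection and the other lists and doses, so a pass there is not independent evidence either. The list of other organs, markers of tissues that an ovary dissection can include, held the pancreatic enzyme genes prss1, CPA1, CEL, ela2l, ela3l and amy2a and the gut genes FABP6 and VIL1. All 7 tested members had higher means at each dose, with median edgeR log2 fold changes of 1.86, 1.84 and 2.68 at 1, 3 and 10 ppm. On the log2 CPM scale that camera used, the medians were 2.04, 1.57 and 1.87 (camera adjusted p 0.16 at each, and adjusted p 0.95 at each with an estimated correlation). At 10 ppm, 6 of 7 passed when adjusted over the list alone and 0 over all loci. CEL stood at 90.3 CPM in 10 ppm replicate 1, against 11.1 and 3.4 CPM in the other libraries at 10 ppm and 0 to 4.56 CPM in the controls. At 1 ppm, 5 of the 8 members had all 3 exposed libraries above the 3 controls. The list's call depended on single libraries: without 0 ppm replicate 3 it passed at all 3 doses (camera adjusted p 0.019, 0.019 and 0.018), and without 10 ppm replicate 3 it passed at 10 ppm (0.0014). These fits without a library used the preset correlation only, under which lists often passed in the random draws.

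The follicle somatic list held the epithelial keratin genes krt8 and krt18a.1 and the transcription factor gene wt1b. Their edgeR log2 fold changes at 3 ppm were 1.06, 1.32 and 1.19 (camera adjusted p 0.72), and 0 of 3 passed over all loci or when adjusted over the list alone. The values came from 3 ppm replicate 2, where krt8 stood at 614 CPM, against 119 and 80.5 CPM in the other libraries at 3 ppm. Krt8 stood next highest, at 372 CPM, in 1 ppm replicate 2. Among the ribosomal proteins, RPS12, RPS10 and rps20 had log2 fold changes of 0.52, 0.22 and 0.50 at 3 ppm (camera adjusted p 0.32), and 1 of the 3, RPS12, passed when adjusted over the list alone. In the stroma list acta2, COL1A1 and FN1 had log2 fold changes of 0.70, 0.61 and 0.20 at 10 ppm (camera adjusted p 0.71), with acta2 passing over the list alone. The ratio of COL1A1 was 0.24 without 10 ppm replicate 3 and that of FN1 -0.07 without 0 ppm replicate 3. The metal handling list held SLC31A1, a copper importer, tfr1b, a transferrin receptor, and the transferrin gene tfa. Their log2 fold changes at 10 ppm were 0.37, 0.83 and 0.75 (camera adjusted p 0.83), and none passed over the list alone. The ratio of tfa was -1.32 without 10 ppm replicate 1. The leukocyte list (c3a.1, mhc1uba, b2m and the untested tnfa) had a median edgeR log2 fold change of 0.29 at 10 ppm, and 0.53 by the log2 CPM fit, with a camera adjusted p of 0.99, and none passed over the list alone. Its member mhc1uba had a ratio of -0.58 at 10 ppm and 0 fragments in 0 ppm replicate 2. The median and the camera direction had opposite signs for the follicle somatic list at 1 and 10 ppm, the metal handling list at 1 and 3 ppm, and the leukocyte and stroma lists at 1 ppm.

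The lists with 1 or 2 named members were too small for the list test. Aromatase (CYP19A1), the enzyme that makes estradiol, was the only named gene of steroid synthesis. Its controls were tight, at 20.1 ± 0.87 CPM, while the exposed groups stood at 38.4 ± 16.1, 30.1 ± 5.41 and 37.6 ± 19.2 CPM at 1, 3 and 10 ppm (SD, n = 3 each). All 3 libraries at 3 ppm lay above the controls, whereas 1 ppm replicate 2 and 10 ppm replicate 1, both at 20.4 CPM, lay within their range. Its edgeR adjusted p was 0.67, 0.93 and 1 over all loci, and adjusted over the list alone, where it is the only member, 0.015, 0.11 and 0.02. Its log2 ratio at 10 ppm was 0.89, and 0.43 without 10 ppm replicate 3. The selenoprotein genes were selenos, described above, and selenop (log2 fold change -0.20, -0.23 and 0.47, the last 0.16 as a ratio without 10 ppm replicate 3). Selenos passed at 1 ppm when adjusted over the list alone (edgeR adjusted p 0.0024), an adjustment that leaves out the authors' selection of its members. The yolk precursor genes vtg2 and vtg3, which are made mainly in liver, ranged from 0.395 to 3060 CPM and from 0.263 to 480 CPM over the 12 libraries, and from 3.65 to 1270 and from 0.995 to 177 CPM within the controls. Both were highest in 10 ppm replicate 1. Without that library the ratio at 10 ppm went from 1.02 to -3.98 for vtg2 and from 1.08 to -3.63 for vtg3. At 1 and 3 ppm the ratios of both were negative and turned positive without 0 ppm replicate 2.

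Of the oocyte genes, zp2.1, an egg coat protein gene, had log2 fold changes of 0.39, 0.16 and -0.21, and npm2a had 0.19, -0.36 and -0.34. The ratio of zp2.1 was 0.04 without 3 ppm replicate 1 and -0.1 without 10 ppm replicate 3. That of npm2a was -0.15 at 1 ppm without 1 ppm replicate 1. The synaptonemal complex gene SYCP1 had log2 fold changes of -0.52, -0.36 and -1.05, and passed at 10 ppm when adjusted over the list alone (0.036), as its only member. Without 0 ppm replicate 2 its ratios were -0.14, -0.02 and -0.66. RRM2, of DNA precursor synthesis, had log2 fold changes of 0.16, -0.21 and -0.37. Its ratio was 0.03 at 1 ppm without 0 ppm replicate 1, and -0.01 and -0.16 at 3 and 10 ppm without 0 ppm replicate 2. In the yolk uptake list CTSB had log2 fold changes of 0.57, 0.67 and 0.08, and apoeb 0.64, 1.03 and 1.01. The ratios of CTSB were 0.30, 0.40 and -0.19 without 0 ppm replicate 1. The ratio of apoeb was 0.13 without 1 ppm replicate 2, 0.21 without 3 ppm replicate 2 and 0.41 without 10 ppm replicate 3. HSP90AA1, a heat shock gene, had a log2 fold change of 2.1 at 3 ppm that came from replicate 2, at 63.1 CPM against 3.17 and 4.53 CPM, and as the only member of its list it passed when adjusted over the list alone (0.032). The immediate early genes klf2b and FOSL2 had values of 2.17 and 0.84 at 3 ppm and were highest in the same library (48.1 and 28.3 CPM). No member of these lists passed over all loci.

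**Figure D2:**
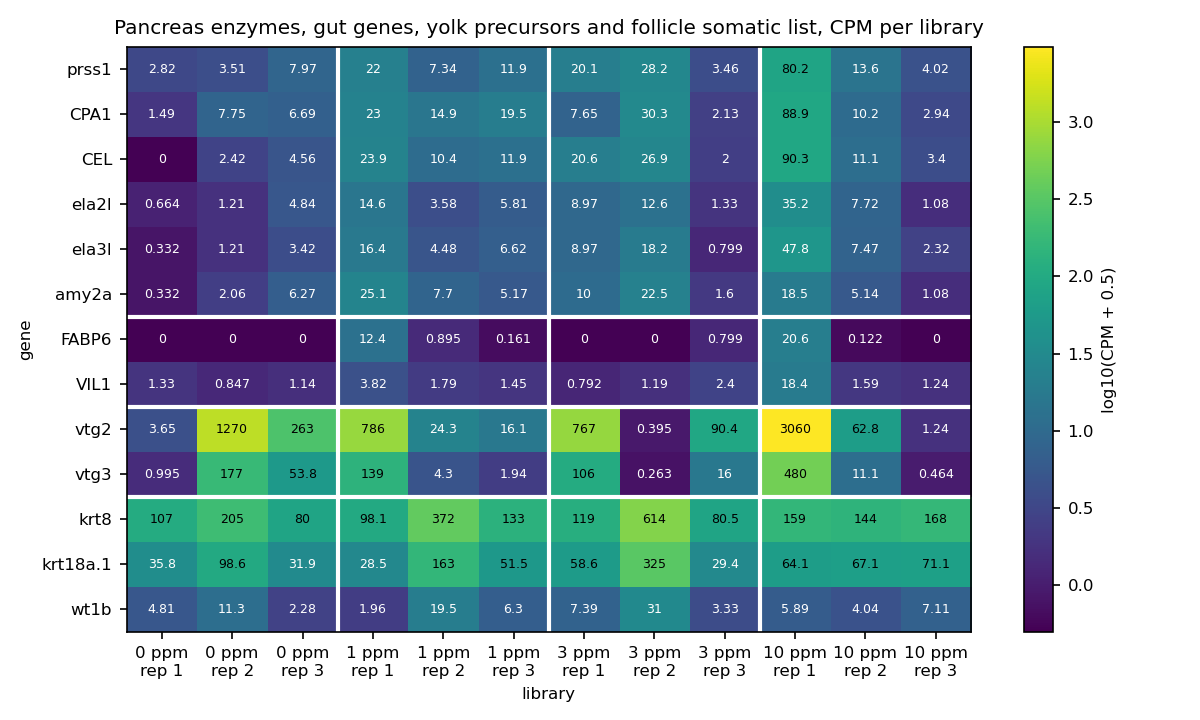
CPM of 13 genes (rows: pancreatic enzymes, gut genes, yolk precursors, follicle somatic list) in each of the 12 libraries (columns), printed in each cell and coloured by log10(CPM + 0.5). CEL reads 90.3 CPM in 10 ppm replicate 1 and 0 to 4.56 CPM in the controls, krt8 reads 614 CPM in 3 ppm replicate 2, and vtg2 varies from 3.65 to 1270 CPM among the controls.

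Since no locus passed at any dose by edgeR, 0 loci were called at more than 1 dose. DESeq2, run for this after seeing the data, called 3: zgc:153499 at 1 and 10 ppm, ENSDARG00000004541 at 3 and 10 ppm, and at 1 and 3 ppm the locus without a name described above, which had 0 fragments in the controls. The log2 fold changes of the doses against the shared controls were correlated across the 15916 loci, which are not independent replicates. Pearson's r was 0.53 for 1 and 3 ppm, 0.44 for 1 and 10 ppm and 0.37 for 3 and 10 ppm, while simulated groups with no effect gave 0.49 for each pair over 40 simulations. The covariance was 0.0628 against 0.0537 ± 0.002 simulated for 1 and 3 ppm, 0.0509 against 0.0535 ± 0.0019 for 1 and 10 ppm, and 0.042 against 0.0539 ± 0.0021 for 3 and 10 ppm (SD over simulations). The share of loci with the same sign at both doses was below the simulated share for every pair, at 62.8% against 66.4% ± 0.4 for 1 and 3 ppm, 62.5% against 66.6% ± 0.4 for 1 and 10 ppm and 59.3% against 66.4% ± 0.3 for 3 and 10 ppm (SD over simulations). Only for 1 and 3 ppm were both r and covariance above the simulated values. The simulation drew each locus independently, whereas real loci can vary together between pools, so its SD cannot judge an excess. It also gave all groups the same spread, so the lower same-sign shares do not show a lack of shared change. Neither an excess nor a lack of shared change is concluded. The controls were too few to be divided between comparisons.

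The authors' deposited table lists 88 loci at 1 ppm against 0 ppm (59 higher, 29 lower), 67 at 3 ppm (50 and 17) and 85 at 10 ppm (67 and 18). It also lists 61 loci between 1 and 3 ppm, 93 between 1 and 10 ppm and 113 between 3 and 10 ppm. The lists against 0 ppm name 174 loci in 240 lines. Of those tested here, 82 of 83, 66 of 66 and 73 of 74 had the same direction, si:dkey-154b15.1 being the exception at 1 and 10 ppm. The authors' calls came from the same libraries, so this shared direction was largely fixed in advance and is not independent evidence. Of the tested loci 50, 30 and 59 had an unadjusted edgeR p under 0.05, and 0 passed at each dose. DESeq2 passed 13 of the 240, in a run added after seeing the data. All 3 exposed libraries lay beyond the 3 controls in the authors' direction for 45, 15 and 32 of the loci, or 51.1%, 22.4% and 37.6%, where chance gives 5% before selection.

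Many of the authors' calls leaned on a single library. With 0.5 CPM added to each group mean, leaving out 1 of the 6 libraries took away over 50% of the log2 ratio for 24 of 88 loci at 1 ppm, 37 of 67 at 3 ppm and 38 of 85 at 10 ppm. The sign turned for 9, 26 and 8 of them. The deciding library was 1 ppm replicate 2 in 16 of the 24, 3 ppm replicate 2 in 29 of the 37 and 10 ppm replicate 1 in 28 of the 38. The loci at 3 ppm that rested on replicate 2 included krt4, clic5a, gja13.2 and slc6a14. Those at 10 ppm that rested on replicate 1 included the digestive enzyme genes CPB1, CELA1, prss59.1 and ctrb.3.

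**Figure D3:**
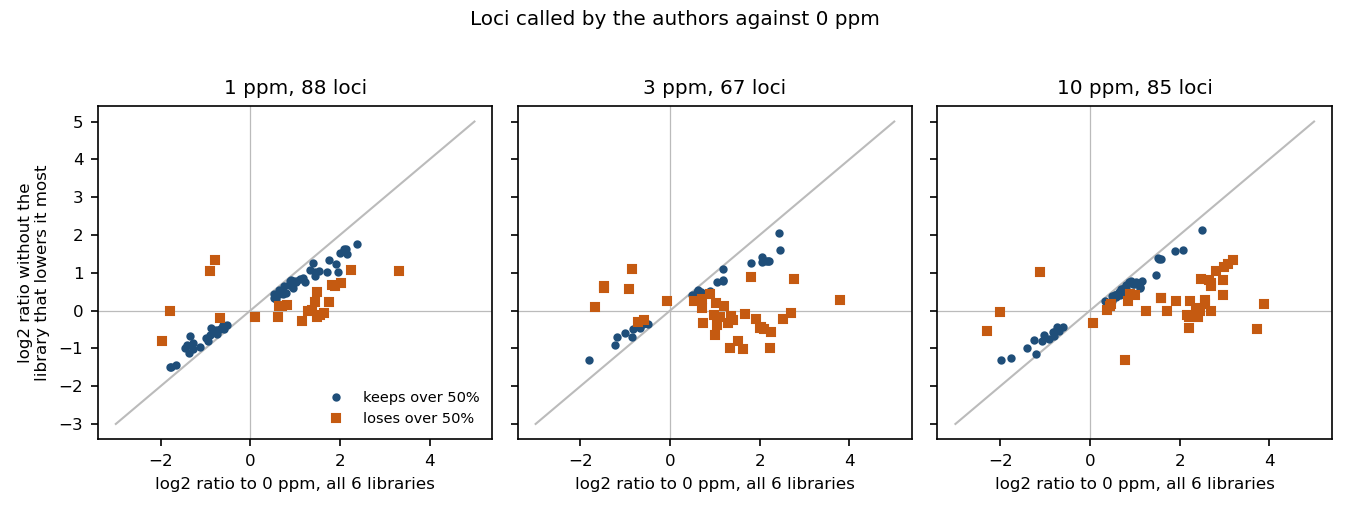
Each point is a locus that the authors' deposited table lists against 0 ppm; the x axis is the log2 ratio of group mean CPM (with 0.5 CPM added) over all 6 libraries and the y axis is the ratio without the library that lowers it most. Orange squares, 24 of 88 loci at 1 ppm, 37 of 67 at 3 ppm and 38 of 85 at 10 ppm, lost over 50% of the ratio, and the grey diagonal marks no change.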

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

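Counts of called loci were 0 at 1, 3 and 10 ppm, in the joint test and for the slope by edgeR with all libraries. They remained 0 with DESeq2 size factors, at least 1 CPM in 3 libraries, limma on FPKM with both added constants, loci not OK removed, only the 6 libraries compared and both other dose scales, and when any single library was left out (0 to 0). Without 1 ppm replicate 2 the smallest edgeR adjusted p was 0.0513 at 1 ppm, against 0.303 with all libraries. In the joint test it was 0.0541 against 0.434. With no filter on low counts the count of called loci was 3 at 1 ppm and 4 in the joint test. DESeq2 gave 19, 2 and 4 at 1, 3 and 10 ppm, 37 in the joint test and 2 for the slope. The cause was not tested. Without 1 ppm replicate 2, 3 ppm replicate 2 and 10 ppm replicate 1, an alternative chosen after the data were seen, the counts were 130 at 1 ppm, 0 at 3 and 10 ppm, 10 in the joint test and 0 for the slope, and 17 of the authors' 240 calls passed instead of 0. The cause was not tested. Leaving 1 library out of each exposed group can be done in 27 ways: 5 gave any call at 1 ppm, all of them without 1 ppm replicate 2, and the highest other count was 96. In the joint test another of the 27 gave more, 14. Of the 130 loci, all 130 had the same sign with all libraries and 99 an unadjusted p under 0.05. Both fits share the controls and the remaining libraries at 1 ppm, so this is not independent evidence for the 130 loci. Gene lists past the threshold were 0 by camera with an estimated correlation, by fry and with DESeq2 size factors, and from 0 to 3 when single libraries were left out (3 without 0 ppm replicate 3, 1 without 10 ppm replicate 3). Loci called at more than 1 dose, and the authors' calls passing here, were also 0 under a threshold of 0.10 and without any single library, the latter chosen after seeing the data for the authors' calls. With DESeq2, added after seeing the data, they were 3 and 13, and the cause was not tested. Of 660 alternative values for named genes, 644 kept direction and side of the threshold, 16 newly passed it and 0 reversed. With a replicate block the counts were 0 for every result it was run for. The numbers were not taken to pair the samples, since deviations of libraries with the same number correlated from -0.19 to 0.21 and only 7 of 18 pairs passed 0.1. A hint of pairing remains: 5 of 36 other pairs passed 0.1, and 8 of 12 libraries correlated best with their own number where equal chance gives 4. At 3727213 to 9669846 fragments and 3 pools a group, the simulations recovered 49% to 56.1% of 2-fold changes, so smaller changes were often not detectable.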

Other observations

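The tests of single-library transcripts were chosen only after the result was seen, except the comparison of 2 libraries for a fixed mixture; the counts over splits of the libraries were fixed before theirs were seen.

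Values of 3 further loci, picked after they were seen, are given here. The immune gene mhc1uba was at 0 CPM in 0 ppm replicate 2, 25.5 and 17.7 CPM in the other controls and 68.9 CPM in 1 ppm replicate 2. Transcripts of hmmr, a gene of the mitotic spindle, stood at 24.6 CPM in 1 ppm replicate 1 and from 140 to 286 CPM in the other 11 libraries. ENSDARG00000053776 stood at 54.3 ± 8.68 CPM (SD, n = 9) in exposed and 32.5 ± 2.93 CPM (SD, n = 3) in control libraries, with log2 fold changes of 0.77, 0.70 and 0.77 at 1, 3 and 10 ppm. It did not pass by edgeR with all libraries. It passed by DESeq2 at 1 ppm (adjusted p 0.0264) and in the joint test (adjusted p 0.022), and by edgeR at 1 ppm without the 3 libraries left out together (adjusted p 0.0352).

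Transcripts of pancreas and gut were high in 10 ppm replicate 1. It was the highest of the 12 libraries for 7 of the 8 named members of the list of other organs, a count that tests no source since it is why this library was singled out. Other exposed libraries were high too: at 1 ppm 5 of the 8 members had all 3 libraries above all 3 controls, and at 3 ppm 0 had. CEL had 219, 58 and 74 fragments at 1 ppm and 78, 204 and 15 at 3 ppm, against 0, 20 and 32 at 0 ppm, before scaling. At 10 ppm, 0 of the 8 members had all 3 libraries above all 3 controls. These members were picked from these libraries and singled out for replicate 1, so a rise shared by the 3 pools stays open. Without replicate 1 the ratios of the 7 tested members ran from 0.09 to 1.46, so a smaller difference in the group mean stays open. Tissue of other organs in the pool may be the source and stays open, since the authors had picked all 8 members from these libraries. For a fixed mixture from a common source, the ratio of 10 ppm replicate 1 to 1 ppm replicate 1 varied 6.51-fold over the 8 members. This passed the limit fixed beforehand for arguing against such a mixture. The excess rested on amy2a: without it the ratio varied 2.9-fold, between that limit and the lower one fixed for a mixture. Single pools can differ by more than counting error, so a fixed mixture shared by 10 ppm replicate 1 and 1 ppm replicate 1 stays open. In 3 ppm replicate 2 the pancreatic members had 96 to 230 fragments, while FABP6 had 0 and VIL1 had 9. VIL1 had 7 to 8 fragments in the controls. In 10 ppm replicate 1 the pancreatic members had 107 to 521 fragments, FABP6 had 119 and VIL1 had 106. These values, read after the data were seen, argue against a single fixed mixture of pancreas and gut across all libraries.

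A mixed set of transcripts, among them the keratin genes krt8, krt18a.1, krt4 and krt94 and also tnfa, HSP90AA1 and FN1, was high in 3 ppm replicate 2. Of the 25 loci called by the authors at 3 ppm that rested on this library and were highest in it, 21 had 1 ppm replicate 2 as the next highest library, where 2.3 would fall to it if all 11 were alike. Among 28 loci of the authors that rested on 10 ppm replicate 1, 0 did so, and 11 had 1 ppm replicate 1 as the next highest library. A preferred next library is thus not particular to the set at 3 ppm. Loci that vary together are not independent, so no p is given. Of krt8, krt18a.1 and wt1b, 0 had all 3 libraries at 3 ppm above the controls, but they belong to the set picked for resting on replicate 2, so a rise shared by the pools stays open. A tissue share that varies from pool to pool may account for the set; a response of some fish at 1 and 3 ppm stays open and was not tested.

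The hypothesis that loci part all 9 exposed from all 3 control libraries more often than other choices of 3 libraries was tested over 15916 loci. The real controls parted 110 loci, 54 with controls lowest and 56 with controls highest. Of the 220 choices of 3 libraries, 134 parted at least as many, the mean was 144.6 and the highest other was 827. The number of such loci is thus no larger than chance gives, which decides nothing about any single locus. The source of the highest count was not tested.

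Other splits of the libraries were set beside each count of calls. For each dose the 10 splits of the 6 libraries are too few for a share under 0.05; the real count was 0 and the highest other was 0 at 1 ppm, 1 at 3 ppm and 0 at 10 ppm. Over 100 draws of the 12 libraries into 4 groups, the real count was 0 for the joint test, the slope, the gene lists, loci called at more than 1 dose and the authors' calls. All 100 draws reach a count of 0 by necessity, so this comparison decides nothing about chance. Of the 99 other draws, 10, 2, 61, 6 and 3 gave any call in these results, and the highest counts were 120, 2, 5, 181 and 12. The source of the draws with many more calls than the real groups was not tested, and which libraries those draws placed together was not examined.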
